A study of Caenorhabditis elegans with 2 samples.

How the data were processed

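The samples were 2 biological replicates of anti-GFP ChIP-seq from whole L1 hermaphrodites of strain OP462, 6 h after synchronization, with chromatin sheared by sonication, per the labels. The replicate numbers come from the labels and both replicates form 1 group. A control experiment is named in the labels as a possible control and was not analysed here, so no background library stands beside the values.

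The authors deposited region lists in narrowPeak format on the ce10 and ce11 assemblies. These were a candidate list for each replicate, a candidate list from the pooled replicates, and an optimal list of peaks. The optimal list was set by the irreproducible discovery rate (IDR), a method that judges how far regions rank alike in replicates. Here the optimal list was the top of the pooled list by signal, so its peaks were not each filtered by replicate. All 8 lists were used. Each candidate list holds 30000 regions, so it ends at a fixed number and includes background. The aligner, the peak caller and their versions are not given in the sources used here. The signal of each region is the value the authors' caller gave, and its scale is not given in the sources used here; replicate signals summed to a median of 1.01 times the deposited pooled signal. The deposited −log10 q values ran from 3.07 to 3.97 in the IDR list and served only to describe it. Signal was used to rank and describe regions, and between replicates to compare ranks and values at the same peak. Read depth is unknown from these lists, so no interval that needs it was computed, and intervals on shares of peaks cover counting error only. Because candidate lists are fixed at 30000 regions, a gene with no candidate has a signal below the end of the list and not a measured 0.

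The annotation was Ensembl release 115 for WBcel235, the same sequence as ce11, and chromosome lengths were checked against the genome used. Lists on ce10 were compared by number, width, signal and chromosome only, and no coordinate was converted. Coordinates are 1-based. Each summit was assigned to the protein-coding gene with the nearest transcription start within 2 kb, and a gene with an assigned summit is called bound, a statement about position and not about regulation. Annotation classes were taken in the order promoter (1 kb upstream of a protein-coding start), 5' UTR, CDS, intron, 3' UTR, noncoding exon and intergenic.

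Chance levels came from 1000 circular shifts of all summits along their own chromosomes, with a random offset per chromosome, which keep the spacing of peaks. The smallest two-sided p from these is 0.0020. Gene lists and families were tested against all other protein-coding genes by Fisher's exact test (two-sided) and against the shifts, with Benjamini-Hochberg adjustment over 23 lists or 84 families, and a list was called only where both adjusted p were under 0.05 in the same direction. Genes are not replicates, so these tests describe how this set of peaks is spread over genes. Families were gene-name prefixes with at least 15 members outside the lists. Of the heterochronic list, 5 members are microRNA genes and were outside the protein-coding comparison. Chromosome shares were compared with the below-threshold regions of the pooled list by Fisher's exact test.

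Motif sites were counted on both strands within 50 bp of summits and in flanks 200 to 500 bp away. The ratio of summit to flank density had a 95% interval from 1000 bootstrap resamples of peaks. All 2080 6-mers were ranked by the same ratio. This ranking was planned as a control for base composition, but ratios differed with GC content, with medians of 1.18 at 3 G or C bases and 1.69 at 4. Only the RUNX forms were compared with 6-mers of equal GC. The trend over signal quintiles was tested with 100000 permutations. A peak matched a replicate when its summit lay inside a region of that replicate, and the region with the nearest summit was taken.

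The groups, tests, lists, motifs, alternatives and the rule for named genes were fixed before the data were examined. The rule named 20 fixed genes, the genes at the 20 strongest peaks, up to 4 bound members per list with the strongest peaks, the 5 genes with the most peaks and the 5 peaks with the largest rank difference between replicates. Further members of a list are named where counts needed it, and those were chosen after their values were seen. The gene at 1 of the 20 strongest peaks is not reported here. Alternatives were the stronger 2780 peaks, the 5560 strongest regions of each replicate alone or of the pooled list, merging of summits within 200 bp, other distances to starts, another gene background, chromosome X left out, other promoter lengths, motif windows and flanks, other matching rules and the ce10 lists. Alternatives used fewer resamples than the values they are set against: 300 shifts for annotation classes, so that their smallest p is larger, and 200 bootstraps for motifs; gene lists kept 1000 shifts. The interval that judges changes in rho also used 200. In the closing section, matched random lists were 10000 draws within 20 bins of gene length and by number of starts, with genes of many starts pooled together. Repeats were counted as 31-mers in the span and in 50 random spans. The explanations that need an untagged, other-factor or control library were labelled open without a deciding test, because no such data were in hand; the values given beside them could not exclude them. For promoters active in any tissue a test was run and its bound, a lower share in other tissues, was met, but that bound was wrong as set, because the activity of the listed promoters in these larvae was not measured, and the explanation was left open.

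The statistics were tested on simulated data. With 5560 simulated peaks over 19973 genes, 10 of 10 planted sets of 40 genes, each with a planted peak at 24, were called, and 0 of 200 random sets were. Apart from the planted peaks, positions were uniform along the chromosomes, and sets were drawn without regard to gene position. The excess of real peaks in promoters and the clustering of gene families were therefore not simulated. The result does not give the rate of false calls in these data, or the power at smaller shares. A planted motif was measured at a ratio of 3.75 over 5000 simulated summits, against an expected 3.79. The expected value used the flank density measured in the same simulation, so only the summit side of the ratio was checked. Background sequence was drawn with 1 base composition throughout, so a difference in GC content between summits and flanks was not simulated. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.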

Results

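RNT-1 is the RUNX-type transcription factor of Caenorhabditis elegans, known from genetics for its part in the divisions of the lateral epidermal seam cells. Its binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole hermaphrodites of a transgenic strain, OP462, that carries RNT-1 fused to green fluorescent protein and a FLAG tag. The animals were first-stage (L1) larvae, 6 h after synchronization, and the tagged protein was precipitated with an antibody against the fluorescent protein. There were 2 biological replicates in 1 group, so the comparisons below are between regions of the genome and between replicates, not between conditions. Read depth is unknown, because the files list regions and not reads, and every signal value is the authors' own, on a scale that the sources do not name. Positions are on the ce11 assembly.

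The authors' optimal list of peaks for tagged RNT-1 held 5560 regions, and most of the strongest lay close to gene starts, those of ribosomal protein genes among them. The highest signal, 3588, was at III:7520731-7520963, 4 bp upstream of the start of cux-7 (WBGene00000854), where the replicates gave 1808 ± 153 (SD, n = 2). It was followed by a region 113 bp upstream of F56G4.6 on chromosome I (3141) and by an intergenic region at V:14055059-14055369 with no protein-coding start within 2 kb (3034). Then came thoc-5, a component of the THO complex of mRNA export (2944), K10D2.5 (2913), and the ribosomal protein genes rpl-35 (2889), rpl-3 (2779) and rpl-15 (2761). Other genes at the 20 strongest peaks were T07F10.3, lrpr-1, F25H9.7, Y65A5A.2, tasp-1, Y56A3A.7, C49A9.10, W04C9.4, sco-1, a cytochrome oxidase assembly factor, ced-5, an engulfment gene, and Y73B6BL.29, with signals from 2717 down to 2260.

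The median peak was 216 bp wide and had a signal of 174, with a range from 71.6 to 3588. The authors' reproducibility threshold, set by the irreproducible discovery rate (IDR), coincided with a threshold on signal: the 5560 peaks were the 5560 strongest regions of the pooled candidate list, and the strongest region left out had a signal of 71.54 against 71.56 for the weakest peak kept. The list therefore does not show that each peak was found in both replicates. No matching region was found in replicate 1 for 133 of the peaks, and none in replicate 2 for 151. The remaining 24440 candidates are called below-threshold regions here. The list on the older ce10 assembly held 5665 peaks, 1.89% more, with 21.9% of peaks on X on both assemblies, a median width of 216 bp on both and a median signal of 171 against 174.

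Over all peaks, signal followed a similar order in both replicates, with the smallest relative spread at the strongest. At rpl-3 the replicates gave 1408 and 1391, at wrm-1 672 and 666, and at the strongest peak of the muscle regulator gene hlh-1 181 and 202. The largest rank differences were at weak peaks: dlk-1, a kinase gene (replicate 1 at 72.5, replicate 2 at 15.5), gldi-8 (60.0 and 15.6), a coding-sequence peak 3865 bp from the start of the katanin gene mei-1, too far to be assigned to it (15.2 and 57.6), syd-9 (14.9 and 40) and fbp-1, a fructose bisphosphatase gene (77.7 and 16.3). Peaks without a matching region in a replicate had no rank there and were left out of the rank differences, among them the strongest peak of lin-39 (270). Ranks ran over 30000 regions with a median signal of 22.4 in replicate 1 and 22.1 in replicate 2, so weak peaks can differ most in rank. Over the 5282 peaks matched in both replicates, Spearman's rho was 0.870 and Pearson's r was 0.976, both across peaks, which are not independent replicates. The median coefficient of variation was 15.6%, replicate 2 gave a median of 0.895 times the signal of replicate 1, and 423 peaks differed more than 2-fold.

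Of the 5560 peaks, 4266 (76.7%, exact Clopper-Pearson 95% interval 75.6 to 77.8%, counting error only) were among the 5560 strongest regions of each replicate. By signal quintile this share was 98.5% in quintile 1, which holds the ribosomal protein peaks named above, and 94.2%, 95.7%, 76.5% and 18.7% in quintiles 2 to 5. The median coefficient of variation went from 8.53% in quintile 1 to 24.3% in quintile 5. Spearman's rho within quintiles 1 to 5 was 0.885, 0.168, -0.215, -0.399 and -0.513, where the quintiles are of pooled signal, so that within a narrow quintile a higher value in 1 replicate goes with a lower value in the other by construction. With 50% reciprocal overlap in place of a summit inside the region, the share in both lists was 64.7%. It was 41.4% among the top 2780 regions of each replicate, a number that cannot hold all 5560 peaks.

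**Figure D1:**
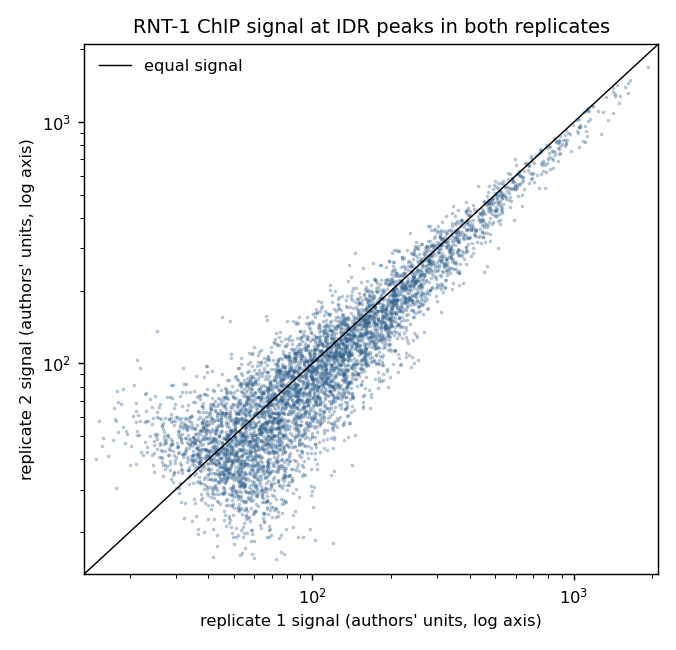
Signal of replicate 1 (x axis) against replicate 2 (y axis), both in the authors' units on log axes, for the 5282 IDR peaks matched in both replicates; each point is a peak and the line marks equal signal. Points lie close to the line at high signal and spread at low signal, with a median coefficient of variation of 8.53% in the strongest quintile and 24.3% in the weakest.

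Peaks sat mainly in promoters and were scarce in coding sequence. Promoters, taken as the 1 kb upstream of a protein-coding transcription start, held 2923 summits (52.6%), 2.39 times the 22% ± 0.608 (SD of shifts) found after shifting all summits along their chromosomes. Coding exons held 2.91% against 20.9% after shifting, introns 16.7% against 28.5%, and 3' UTRs 0.504% against 2.42%. Noncoding exons were higher at 3.35% against 2.13%, and 5' UTRs at 1.42% against 1.1% (adjusted permutation p = 0.0373). The adjusted permutation p was 0.00280 for promoters, coding exons, introns, 3' UTRs and noncoding exons. Before adjustment each stood at 0.0020, the smallest that 1000 shifts allowed. Intergenic sequence outside promoters held 22.6% of summits, against 23% after shifting (adjusted permutation p = 0.565).

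The below-threshold regions had another distribution, with 23.1% in promoters and 37.5% in coding exons. For 2 classes this comparison differed from that with shifts. Intergenic sequence held 14.7% of these regions against 22.6% of peaks (odds ratio 1.69, Fisher's exact test, adjusted p = 4.98e-43). For 5' UTRs the shares were 1.54% and 1.42% (Fisher's exact test, adjusted p = 0.544). The median distance from summit to the nearest protein-coding start was 618 bp for peaks and 1134 bp for below-threshold regions. Of the 2576 peaks within 500 bp of a start, 85.2% were on its upstream side, against 42% of such below-threshold regions. With promoters extended to 2 kb, the ratio to shifted summits was 1.71.

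**Figure D2:**
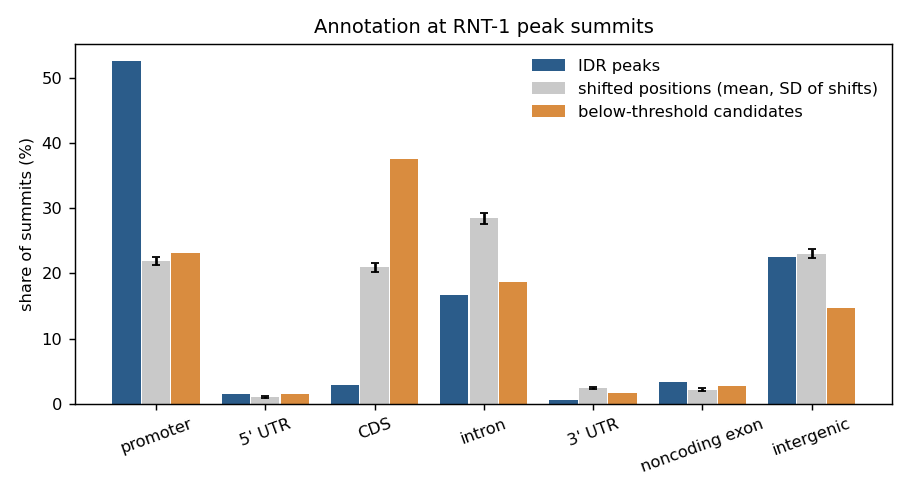
Share of summits (y axis, %) in each annotation class (x axis) for the 5560 IDR peaks, for circularly shifted summits (mean, with bars for the SD over 1000 shifts) and for the 24440 below-threshold regions. Promoters hold 52.6% of peaks against 22% of shifted summits, and coding exons 2.91% against 20.9%.

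The X chromosome carried the highest density of peaks, 68.7 per Mb, and chromosome V the lowest, 40.5 per Mb. Chromosomes I, II, III and IV had 63.0, 54.9, 65.1 and 46.3 per Mb. X held 21.9% of peaks and 19.1% of below-threshold regions (odds ratio 1.19, two-sided Fisher's exact test, p = 2.9e-06). The middle section of each autosome, equal in length to either end and where broadly expressed genes are known to be concentrated, held 47.1% of autosomal peaks and 43.3% of below-threshold regions (odds ratio 1.16, exact p = 6.52e-06). In the stronger 2780 peaks the odds ratios were 1.08 (exact p = 0.141) for X and 1.06 (exact p = 0.206) for the middle of the autosomes, so neither difference passed the test there.

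With each peak given to its nearest start, genes of body wall muscle were bound more often than any other list: 29 of 34 had a peak (85.3%), against 7.27 after shifting, a ratio of 3.99. The strongest muscle peaks were at act-1, an actin gene (514; replicates 255 ± 40.3, SD, n = 2), unc-22, which encodes twitchin (394; 197 ± 16), hlh-1, the homologue of MyoD (386; 191 ± 14.7), and unc-27, a troponin I gene (374; 186 ± 21.6). Myosin heavy chain genes were included, with 3 peaks each at unc-54 and myo-3, and 14 of the 29 genes had more than 1 peak. The 5 without a peak were dys-1, egl-19, tni-1, tni-3 and unc-98. The odds ratio was 28.3 (Fisher's exact test, adjusted p = 7.26e-17; shifts, adjusted p = 0.0115). The list kept its call in all 10 alternative settings, 1 of which is the same set of peaks, with 61.8 to 91.2% of members bound; p against shifts stayed at or near the smallest possible value and does not measure stability.

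Ribosomal protein genes were bound at 43 of 79 (54.4%), 6.40 times the 6.72 after shifting (adjusted p = 4.21e-13 by Fisher's exact test and 0.0115 by shifts). Their peaks were the strongest of the lists called as higher: the median best rank of a bound member was 640 of 5560, and 28 of the 43 had a peak in the strongest quintile. For muscle genes that median was 1984, with 6 of 29 in the strongest quintile. The strongest ribosomal peaks were at rpl-35 (replicates 1444 ± 22.9, SD, n = 2), rpl-3 (1400 ± 12.3), rpl-15 (1389 ± 158) and rps-1 (846 ± 15.8). With every gene that has a start within 2 kb of a peak counted, and not the nearest alone, 74 of 79 ribosomal protein genes were bound (93.7%), more than the 31 of 34 muscle genes (91.2%) under that rule.

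Wnt pathway genes were bound at 14 of 26 (53.8%), 2.68 times the shifted number (adjusted p = 1.29e-04 by Fisher's exact test and 0.0115 by shifts). They included the Dishevelled homologues mig-5 (1496; replicates 749 ± 4.25, SD, n = 2), dsh-1 (281; 142 ± 47.8) and dsh-2, the beta-catenin genes wrm-1 (1330; 669 ± 4.13), bar-1 and sys-1 but not hmp-2, and the TCF homologue pop-1 (298; 148 ± 44.5). None of the Wnt ligand genes on the list (cwn-1, cwn-2, egl-20, lin-44, mom-2) had a peak. In the stronger 2780 peaks the list fell to 30.8% bound and lost its call (adjusted permutation p = 0.138 by shifts, range over settings 0.00919 to 0.138). Fewer genes of any kind were bound there, 2051 of 19973 against 3424. By Fisher's exact test the list passed in each of the 10 alternative settings (adjusted p at most 0.0171).

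Heterochronic genes, which time larval development, were bound at 8 of 11 (72.7%, 2.53 times shifted; adjusted p = 3.43e-04 by Fisher's exact test and 0.0184 by shifts). The strongest peaks were at lin-14 (348; replicates 172 ± 9.70, SD, n = 2), lin-41 (318; 151 ± 34.2), lin-28 (303; 155 ± 42.5) and daf-12 (281; 143 ± 54), and blmp-1, lin-29 and lin-46 had none. This list rested on both replicates: the strongest regions of replicate 1 alone gave 7 of 11 (adjusted permutation p = 0.0766 by shifts) and those of replicate 2 alone 7 of 11 (0.0656), and over all settings the adjusted p ran from 0.00919 to 0.376. Without chromosome X, which holds lin-14, hbl-1 and daf-12, it was 5 of 8 (adjusted permutation p = 0.158), and with starts within 1 kb 5 of 11 (0.255).

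Cell cycle genes were bound at 9 of 23 (39.1%, 2.71 times shifted; adjusted p = 0.0296 by Fisher's exact test and 0.0306 by shifts), among them efl-1, an E2F homologue (1061; replicates 537 ± 41.7, SD, n = 2), lin-23, an F-box gene (525; 263 ± 12.4), cye-1, the cyclin E gene (462; 230 ± 21.7), and cdc-14, a phosphatase gene (354; 180 ± 25). The cyclin-dependent kinase gene cdk-1 (149) and the cyclin D gene cyd-1 (95.2) were bound, while cdk-2, cdk-4, the cdc-25 genes and lin-35, the Rb homologue, had no peak. The start of lin-35 (I:5807709) lies in the span around rnt-1 that holds no candidate region, described below. From replicate 1 alone the share was the same, 9 of 23, but the adjusted permutation p by shifts was 0.0643, so the call was lost without replicate 2. The list was called in 5 of 10 settings; with every gene within 2 kb counted (47.8%) or with candidate genes as background (50%) it passed the shifts and missed only Fisher's exact test (adjusted p = 0.0619 and 0.101).

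Chemoreceptor genes were nearly free of peaks: 13 of 1302 were bound (0.998%), 0.0938 times the 139 after shifting (adjusted p = 2.81e-87 by Fisher's exact test and 0.0115 by shifts). The strongest peaks assigned to them were at srh-16 (1164), sri-5 (1008), srh-2 (813) and sre-23 (512). Across all 19973 protein-coding genes, 3424 (17.1%) had a peak within 2 kb of a start, against 2793 ± 41.8 (SD of shifts) after shifting. Of the 23 lists fixed before the data were examined, the 5 above were called higher and chemoreceptors lower.

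**Figure D3:**
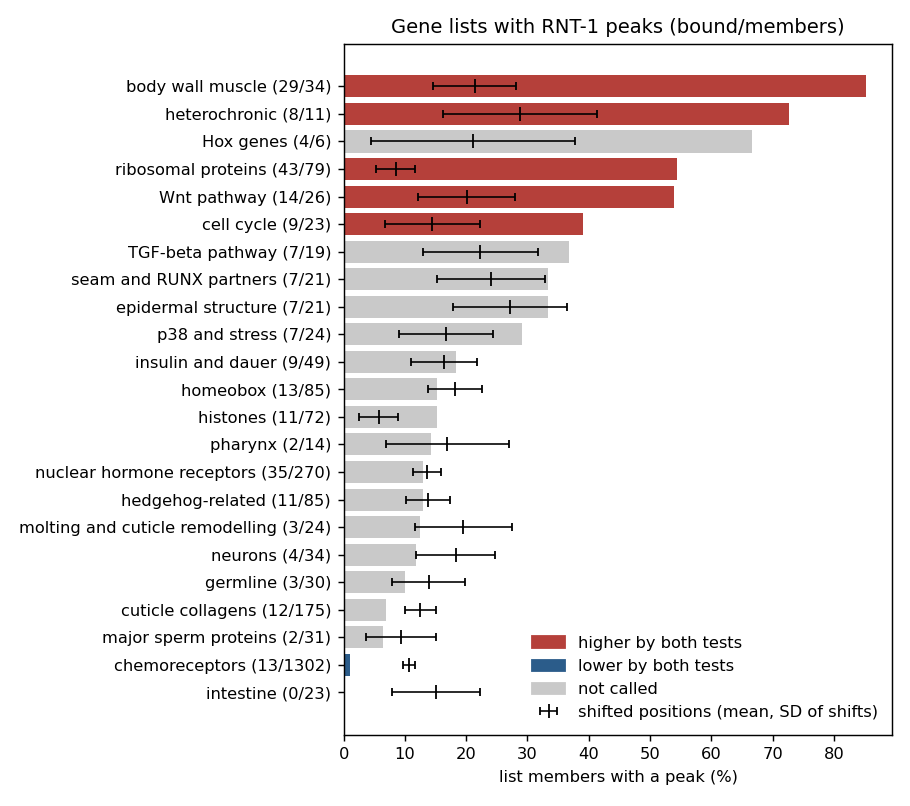
Share of each gene list's protein-coding members with an IDR peak (bars; x axis, %), with bound and total members in parentheses, and the share after 1000 circular shifts (black marks, mean and SD of shifts). Body wall muscle reaches 85.3% and ribosomal proteins 54.4%, chemoreceptors stay at 0.998%, and none of the 23 intestine genes has a peak.

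Lists of epidermal and other tissues were not called. Seam cell genes and partners of RUNX gave 7 of 21 (adjusted p = 0.131 by Fisher's exact test and 0.742 by shifts), with the strongest peaks at ajm-1, pop-1, elt-1 and cki-1. Epidermal structure genes gave 7 of 21, led by dpy-23 (597), vab-10 (428), ajm-1 (330) and hmr-1 (204), with adjusted p of 0.131 and 0.911. The 23 intestine genes had no peak, among them elt-2, ges-1 and the vitellogenin genes vit-1 to vit-6, against 3.48 after shifting (adjusted p = 0.0601 by Fisher's exact test and 0.0965 by shifts). Pharynx genes gave 2 of 14 (peb-1, tbx-2), neuronal genes 4 of 34 (ric-19, snb-1, unc-64, egl-21), germline genes 3 of 30 (spo-11, gld-2, syp-2) and major sperm protein genes 2 of 31 (msp-50, msp-57), each with adjusted p of at least 0.248.

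Hox genes were bound at 4 of 6: lin-39 (270), mab-5 (252), ceh-13 (187) and egl-5 (113), with nob-1 and php-3 unbound. They passed Fisher's exact test (adjusted p = 0.0296) but not the shifts (0.0868). From replicate 2 alone, 5 of 6 were bound and the shifts gave 0.0383, so that list was called there. Cuticle collagens gave 12 of 175, led by col-94, col-63, col-181 and col-72 (adjusted p = 4.14e-04 by Fisher's exact test and 0.0689 by shifts); with starts within 1 kb they were called lower, at 6 of 175 (0.0383 by shifts; range over settings 0.0383 to 0.727).

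The remaining lists passed neither test. TGF-beta pathway genes gave 7 of 19 (sma-9 at 578, daf-14 at 455, daf-5 at 254, daf-4 at 229), insulin and dauer genes 9 of 49 (ins-13 at 1357, ins-39 at 1019, daf-16 at 408 with 6 peaks, daf-15 at 236), and p38 and stress genes 7 of 24 (vhp-1 at 457, skn-1 at 271, hsp-16.2 at 111, nsy-1 at 95.8). Nuclear hormone receptors gave 35 of 270 (nhr-19, nhr-47, nhr-49, nhr-1), homeobox genes 13 of 85 (ceh-38, ceh-5, ceh-18, lin-39), hedgehog-related genes 11 of 85 (ptr-24, grl-3, ptc-1, grl-26), and molting genes 3 of 24 (pan-1, bli-4, nhr-23). Histone genes gave 11 of 72 (his-37, his-68, his-24, his-72), where the tests pointed in opposite directions: the odds ratio was 0.871 and the ratio to shifts 2.68, with adjusted p of 0.861 and 0.0689. With every gene that has a start within 2 kb counted, 27 of 72 histone genes were bound (37.5%), and the list was still not called.

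A search over 84 gene-name families not covered by the lists called 15. Higher were vps (14 of 31) and sec (9 of 19) of vesicle transport, npp nucleoporins (10 of 26), mrps mitochondrial ribosomal proteins (12 of 29), dnj DnaJ chaperones (12 of 29), cyn cyclophilins (7 of 16) and wdr WD-repeat proteins (7 of 15). The name classes unc (44 of 69), let (13 of 32) and tag (20 of 57), which share a phenotype or naming convention and not a protein fold, were also higher. Lower were clec C-type lectins (9 of 240), fbxa F-box proteins (5 of 170), ugt glucuronosyltransferases (1 of 67), and irld and oac genes (0 of 56 each). Among families not called, mrpl (13 of 41, 2.82 times shifted) and eif (9 of 25, 3.18 times) passed the shifts (adjusted permutation p = 0.0240 each) but not Fisher's exact test (0.0666 and 0.0831), and rab (5 of 19) and vha (6 of 19) passed neither. Other families passed Fisher's exact test but not the shifts. Of these, fbxb, math, srlf, sdz, nlp, fbxc and cyp were on the lower side, and lin and pqn on the higher side.

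For unc genes the ratio to shifts was 2.43 (adjusted p = 5.96e-16 by Fisher's exact test and 0.0210 by shifts), and for mrps it was 4.71 (0.0118 and 0.0210). From replicate 1 alone, cyn (6 of 16, adjusted permutation p = 0.0592 by shifts), let (12 of 32, 0.0746) and ugt (1 of 67, 0.0524) lost their calls; from replicate 2 alone, oac (1 of 56, 0.0687), ugt (2 of 67, 0.112) and wdr (7 of 15, 0.0559) did. In the stronger 2780 peaks, 4 of the 15 calls remained, those of clec, npp, unc and vps.

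The rnt-1 gene itself had no peak. The nearest IDR peak to rnt-1 (WBGene00004393, I:5776093-5788611) was 32022 bp from its start, and no candidate region of any rank lay within 10 kb. The gene for its binding partner, bro-1, had no assigned peak, with the nearest 3092 bp away, and unc-119, mutated in this strain, had no IDR peak and 2 below-threshold regions within 10 kb; from replicate 1 alone unc-119 gained a peak. Among seam and epidermal regulators, elt-1, a GATA factor gene, had 4 peaks (strongest 270; replicates 135 ± 38.6, SD, n = 2), cki-1, a cyclin-dependent kinase inhibitor gene, had 2 (241; 122 ± 1.29), pop-1 had 1, and egl-18 had 1 weak peak (90.8; 47.7 ± 27.7) that was not among the strongest regions of replicate 2. No peak was assigned to elt-6, ceh-16, nhr-25, lin-22, elt-3 or blmp-1, nor to elt-2 of the intestine or the p38 kinase gene pmk-1.

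Of the timing genes, lin-14 had 5 peaks, one at X:11467434-11467534 in an intron; lin-28 had 2, the stronger at I:8409830-8409939 in its 5' UTR; and hbl-1 had 1, 1878 bp upstream of its start (167; 82.0 ± 6.25, SD, n = 2). The Hox genes mab-5 and lin-39 had 1 and 3 peaks. The strongest at lin-39, 49 bp upstream of a start, had no matching region in replicate 1. A match needs the summit inside a region, so this does not show that signal was absent in replicate 1. Replicate 2 gave 124 there, against 270 in the pooled list. The genes with the most peaks were mnk-1 (8), unc-62, a Meis-type homeobox gene (7), mak-1 (7), mdl-1 (6) and unk-1 (6), and 8 genes were tied at 6. Of the bound genes, 2817 had 1 peak and 607 had more.

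**Figure D4:**
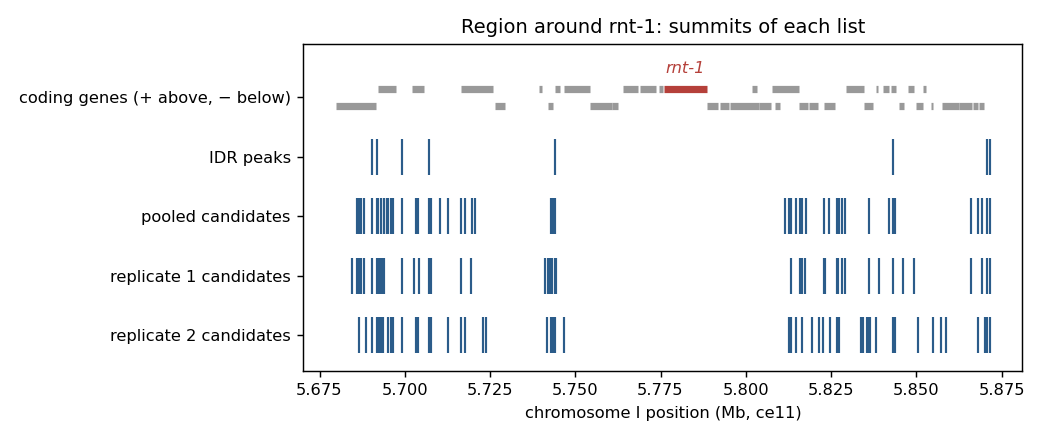
Chromosome I around rnt-1 (x axis, position in Mb on ce11), with protein-coding genes drawn by strand and the summits of IDR peaks and of the pooled, replicate 1 and replicate 2 candidate lists as vertical lines. No summit of any list falls between 5746705 and 5811631, a span that contains rnt-1.

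The RUNX core site TGYGGT (Y is C or T) was present within 50 bp of 581 of 5560 summits (10.4%). It occurred 1.1 times per kb at summits and 0.542 times per kb in flanks 200 to 500 bp away, a ratio of 2.03 (95% bootstrap interval over peaks 1.85 to 2.21), against 1.30 (1.24 to 1.37) at below-threshold regions. Other short sequences rose more: GAGAGA had a ratio of 6.04 (5.46 to 6.63) and occurred at 30.8% of summits, and the E-box CACGTG had a ratio of 2.82 (2.44 to 3.23). The SMAD-type site GTCTAG stood at 1.47 (1.23 to 1.71) and the nuclear receptor site AGGTCA at 1.29 (1.11 to 1.49). The AP-1 site TGASTCA was not distinguishable from its flanks at 1.04 (0.772 to 1.33), the GATA site AGATAA was lower at 0.883 (0.788 to 0.983), and the homeobox site TAATTA was the lowest at 0.187 (0.143 to 0.235). Mean GC content was 50% at summits and 35.7% in flanks in the strongest quintile, and 44.8% and 35.4% in the weakest. AT-rich sites such as AGATAA and TAATTA can have a low ratio from composition alone, and they were not compared with 6-mers of equal GC. Ratios of the other sites can be raised by composition. The median ratio was 1.18 over 6-mers with 3 G or C bases, the class of GAGAGA, GTCTAG and AGGTCA. It was 1.69 over those with 4, the class of CACGTG. The AGGTCA interval includes its class median, while those of GAGAGA, GTCTAG and CACGTG lay above theirs.

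Among all possible 6-mers, 390 had a higher ratio than the RUNX core. The 6-mers with the highest ratios were ACGCAG (7.97), GACGCA (7.60), GCGCGC (7.45), ACGCGC (7.17) and AGACGC (6.90). The RUNX form TGCGGT had a ratio of 2.72, above 88.6% of 6-mers with the same number of G and C bases, and TGTGGT one of 1.70, at percentile 85.5 of its own class. The AGATAA ratio was no longer distinguishable from 1 with windows of 25 bp (0.926, 0.794 to 1.06) or 100 bp (0.959, 0.881 to 1.03), nor with flanks 500 to 1000 bp away (0.952, 0.853 to 1.08) or at peaks over 500 bp from a start (0.921, 0.786 to 1.07). At peaks within 500 bp of a start the intervals of the SMAD-type site (1.16, 0.854 to 1.51) and the nuclear receptor site (1.27, 0.940 to 1.62) also included 1. The interval of the nuclear receptor site did so with the farther flanks too (1.17, 0.974 to 1.31).

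The share of summits with a RUNX core declined from the strongest peaks to the weakest, from 12.1% in quintile 1 through 10.5%, 10.4% and 9.71% to 9.53% in quintile 5 (two-sided permutation test for trend, p = 0.0448). GACGCA declined more steeply, from 22.9% to 10.9% (p = 2e-05, the smallest the permutations can give), while GAGAGA was highest in quintile 2 at 35.2% and stood at 29.9% and 26.3% in quintiles 1 and 5 (p = 0.00252). Only the RUNX trend was planned: the others were added after the values were seen, and GACGCA was picked from the ranking of 6-mers on the same peaks. Within the stronger 2780 peaks the RUNX difference between the outer quintiles was 2.16 percentage points against 2.52 in all peaks, and the trend did not pass the permutation test (p = 0.140). In the strongest regions of replicate 2 alone the difference was 4.68 points (permutation p = 6e-05), and in those of replicate 1 alone 3.15 (p = 0.0210). Peaks are not replicates, so these p-values describe these peaks only. The trend tests did not adjust for GC content at summits, which fell from 50% in quintile 1 to 44.8% in quintile 5. Nor did they adjust for nearness to a protein-coding start: 64.2% of quintile 1 and 38.2% of quintile 5 lay within 500 bp. The RUNX ratio of summits to flanks was 2.34, 1.91 and 2.15 in quintiles 1 to 3 and 1.70 in quintile 5, without a steady fall. Whether base composition accounts for the RUNX decline was not tested.

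**Figure D5:**
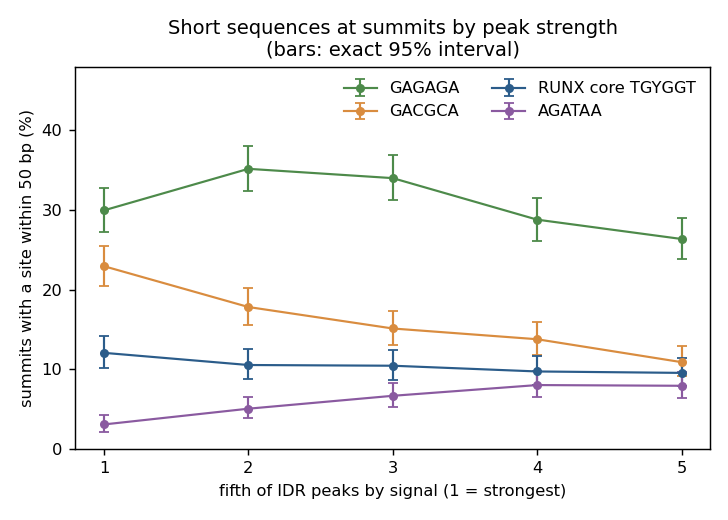
Share of summits with each short sequence within 50 bp (y axis, %) by quintile of IDR peaks in order of signal (x axis, 1 is the strongest), with bars for exact 95% intervals that cover counting error only. GACGCA goes from 22.9% to 10.9%, the RUNX core from 12.1% to 9.53%, and AGATAA from 3.06% to 7.91%.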

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

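The comparison of noncoding gene classes was chosen after the peaks had been seen. Genes that do not encode proteins were outside the comparisons above, and several classes of them had more peaks nearby than shifted summits gave. No biological explanation was tested, and each class named here had an adjusted permutation p of 0.00250 by circular shifts over 10 classes. Transfer RNA genes had 277 IDR peaks within 500 bp of a start, against 31.8 ± 5.83 (SD of shifts), and 305 of 612 such genes had a peak. Of those 277 peaks, 217 lay over 500 bp from any protein-coding start. Small nucleolar RNA genes had 139 peaks against 18.6 ± 4.44, and 63 of these were in the strongest quintile. Small nuclear RNA genes had 34 against 6.19 ± 2.76, microRNA genes 42 against 13.0 ± 3.78, and long intergenic RNA genes 26 against 10.9 ± 3.38. The annotation's general class of noncoding RNA genes had 1070 against 343 ± 21.3. Over 500 bp from any protein-coding start lay 92 of the small nucleolar, 26 of the small nuclear, 28 of the microRNA, 13 of the long intergenic and 730 of the general-class peaks. Shifts do not allow for the excess of peaks at protein-coding promoters (2.39 times shifted), so peaks shared with such promoters can raise these ratios. In the other direction, pseudogenes had 41 peaks against 105 ± 12.3 and piRNA genes 110 against 231 ± 34.3, though against below-threshold regions piRNA genes were higher (1.98% of peaks, 1.53% of those regions).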

How the results depend on the processing

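No alternative here was chosen after the values were seen, but the interval used to judge the percentile of the RUNX 6-mers was. The stronger 2780 peaks, 50% of the set by construction, changed several results: 3 lists (body wall muscle, ribosomal proteins, chemoreceptors) and 4 families were called instead of 6 and 15, the odds ratios were 1.08 for X and 1.06 for the middle of the autosomes, and the RUNX difference was 2.16 percentage points. The promoter ratio (2.72) and the RUNX ratio (2.14) stayed past their tests there. With 50% reciprocal overlap the replicate rho was 0.843 and the share of peaks in both top lists 64.7%; that share was 78.1% with summits within 100 bp, 41.4% at the top 2780 and 91.7% with a top list 2 times as long as 5560, the last 2 set by the number allowed. From either replicate alone, the ranges were 2.32 to 2.41 for the promoter ratio, 1.13 to 1.14 for X, 1.14 to 1.22 for the middle of the autosomes, 4 to 6 lists, 12 to 15 families, 1.98 to 2.03 for the RUNX ratio and 3.15 to 4.68 percentage points for the RUNX difference. Leaving out a replicate gives no agreement between replicates, and the number of peaks was then fixed at 5560. The pooled list's 5560 strongest regions are the IDR set itself, so that alternative changed nothing by construction, and merging left 5558 peaks. Of the bound named genes, 3 lost their peak from replicate 1 alone, 8 from replicate 2 alone, 20 in the stronger 2780 peaks, 20 with starts within 1 kb and 40 within 500 bp. No called result reversed direction in the alternatives tried, but lists without a call crossed the level of other genes: homeobox genes went from 15.3% to 18.8 and 20% in the single replicates, and p38 and stress genes from 29.2% to 16.7% in replicate 2. Except for the construction named, the cause of these changes was not tested. Read depth, which would set how many weak peaks can be found, is unknown.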

Other observations

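The values in the next 2 paragraphs and, after those, the tests of other tissues, of RUNX sites at muscle peaks, of mitochondrial ribosomal genes and of the transgene, with the interval on long spans, were chosen after the result was seen. Apart from RUNX core sites at the summits and promoters active in any tissue, no biological explanation was tested.

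Of the microRNA genes that time larval development, lin-4 had a peak 449 bp from its annotated start (94.4; replicates 48.4 ± 18.1, SD, n = 2) and let-7 had one 1851 bp away (415; 204 ± 32), while mir-48, mir-84 and mir-241 had none within 2 kb. These distances are from unlike features: the interval used for let-7 (X:14743590-14745321) is far longer than the hairpin, and the other genes are annotated as hairpins.

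Weak and strong peaks differed in their surroundings. The GATA site AGATAA was found at 3.06% of summits in the strongest quintile and at 7.91% in the weakest (permutation test for trend, p = 2e-05, the smallest the permutations can give), the reverse of the RUNX core and GACGCA. Peaks within 500 bp of a protein-coding start made up 64.2% of the strongest quintile and 38.2% of the weakest, and the mean GC content at summits went from 50% to 44.8%, with 35.7% and 35.4% in the flanks. Ribosomal protein genes had their best peak in the strongest quintile in 65.1% of bound members and muscle genes in 20.7% (two-sided Fisher's exact test, p = 2.75e-04).

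Ribosomal protein genes held strong peaks. The RUNX core was within 50 bp of 4.55% of their 44 peaks (exact 95% interval 0.555 to 15.5%), against 10.5% of the other peaks (two-sided Fisher's exact test, p = 0.317), which argues only against a share 2 times that of the others, the bound set beforehand, and leaves a smaller excess open. GC content as the whole cause of passing IDR is argued against only narrowly: candidate regions near ribosomal genes passed with an odds ratio of 2.03, and within 10 strata of summit GC it was 1.53 (95% interval 1.03 to 2.27). The strength of the peaks was not compared within strata of GC, so GC content as a cause of their high signal is left open. As a hypothesis, the signal may be common to broadly used promoters whatever the tagged protein: 41.4% of mrps genes were bound too, and mrpl (31.7%), eif (36%), vha (31.6%) and rab genes (26.3%) also stood above the 17.1% of all genes, though none of these 4 was called and only mrpl and eif passed the shifts. That, written with no test at hand that could exclude it, cannot be told apart from binding by RNT-1, because no untagged or other-factor library was analysed here.

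Body wall muscle genes were bound at 29 of 34. Gene length and number of start sites, as binned, did not account for it: in 10000 random lists matched on both, the mean was 7.93 and the highest 18. Genes with many starts were pooled in the matching, so differences in length within a bin and in starts among those genes were not matched. An excess of the RUNX core at the summits is argued against, since it was within 50 bp of 1.79% of 56 muscle peaks (exact 95% interval 0.0452 to 9.55%), against 10.5% of the others. Genes of 5 other tissue lists were bound at 13.1% of 122 (two-sided Fisher's exact test, p = 3.32e-15; the first version of this test took only 3 of those lists, at 8.45%, and epidermal structure genes alone stood at 33.3%), but peaks at promoters active in any tissue cannot be told apart from peaks special to muscle, because promoter activity in these larvae was not measured. As a hypothesis, the muscle peaks may come through another factor or another site, which was not tested.

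The span without candidates around rnt-1 was 67.6 kb in the pooled list, 68.9 kb in replicate 1 and 65.9 kb in replicate 2, with 14 protein-coding genes inside the pooled span and a median spacing of 1.43 kb between candidates. Sequence that cannot be placed uniquely is argued against: 2.39% of its 31-mers occur more than once in the genome, against a median of 8.89% in 50 random spans of chromosome I. For chance, 4.04% of protein-coding genes start in a span at least as long in the pooled list, which is under the 5% set beforehand as counting against chance, and the first label said so; a 95% bootstrap interval over spans, added after that value was seen because a bound must be passed by more than its spread, reaches 5.16% (from 2.96%), so chance is left open here. In the replicates the values were 3.02% (2.13 to 4.0%) and 3.10% (2.21 to 4.15%), both intervals under 5%, so the verdict rests on the list chosen. These shares count all genes of a list and are not probabilities of chance. Spacings at least as long as the span, the span included, numbered 62 in the pooled list, 46 in replicate 1 and 52 in replicate 2. As a hypothesis, copies of the transgene may have raised the control over this span and hidden regions there; the 67.6 kb length cannot be told apart from a true absence of binding, because the control was not analysed here.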
